A study of Mus musculus with 15 samples.

How the data were processed

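Polyadenylated RNA of livers, HCC nodules and thymi of C57BL/6J mice was sequenced on an Illumina NovaSeq instrument with a stranded library kit, per the labels' protocols. The authors deposited a table of 13938 protein-coding genes and a table of 29124 transcripts, both in FPKM per the file headers. Per the submitters' processing notes, FastQC 0.11.7, cutadapt, HISAT2 2.1.0 and StringTie 1.3.3 were used with the genome build mm10; the annotation release, the strand setting and the rule behind the choice of genes are not given in the sources used here. Of the versioned gene identifiers 87.7% were found in GENCODE M21, and all of these genes had the same start and end there. Without the version 99.8% were found, and the coordinates of the added genes were not compared. Coordinates are those of the deposited table, on mm10. The values are FPKM and no read counts were used, so the depth of each sample is unknown. No interval for counting error was computed, and precision rests on the 3 samples per group.

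Groups were taken from the sample titles, since the tissue field of the thymus samples names liver or nodule. The table columns of livers carry the numbers 2, 3 and 5, while their titles name mice 2, 3 and 3, so livers 3 and 5 were used as normal livers without a link to a thymus. Model mice 8, 15 and 25 gave 3 samples each. The numbers pair the samples of model mice because the titles name the same animal: deviations from the group mean correlated at 0.311, 0.261 and 0.325 across genes between the big and small nodule of a mouse, and from -0.243 to -0.0457 between mice. Nodule means and thymi of a mouse correlated at 0.0643, 0.0853 and 0.0536.

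All tests used log2(FPKM + 1), so fold changes are on that scale. Genes with an FPKM of at least 1 in at least 3 of the samples of a comparison were kept. Tests were those of limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and an adjusted p under 0.05. Nodules against livers compared 3 livers with 3 mice, each the mean of the log2 values of its big and small nodule, because the animal is the replicate. Model thymi were compared with normal thymi, and big with small nodules, 3 against 3. The main test of nodule size did not use the pairing by mouse, which entered as an alternative. The organ comparison tested the interaction of organ and model over 12 values (3 livers, 3 nodule means, 6 thymi). Means ± SD are of FPKM over 3 samples or mice.

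Gene lists, 52 in all, were written from textbook knowledge of liver, tumour and thymus; those for the organ concerned were tested where at least 4 members passed the filter. The test was camera with a preset correlation of 0.01, adjusted over the lists of a comparison, then camera with an estimated correlation (which uses statmod 1.5.0) and fry. The design, lists and rule for named genes were fixed before the data were examined. The rule names, per comparison, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the groups (no such condition for the interaction), or, where none passed, the 3 smallest p each way. It left out predicted genes and immunoglobulin and T cell receptor segments. It also names up to 4 members per list by adjusted p, a fixed set of genes per organ, and Alb, Apoa1, Rag1 and Cd3e as a check of labels. Genes outside it are said to be named after their values were seen.

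Simulated data had the real mean of each gene per organ and its real spread within groups, with genes and samples that varied independently. The 2 nodules of a mouse, which deviated alike in the real data, were thus independent there. The shares recovered for nodules against livers and for the interaction may therefore be too high. At each size 50 genes were changed, drawn from those with a mean of at least 5 FPKM. The procedure was tested on these data. For nodules against livers it recovered 28% of 1.5-fold, 68% of 2-fold, 92% of 4-fold and 100% of 8-fold changes, with 8 false calls among 10669 genes. For thymus the shares were 28%, 66%, 98% and 98% with 4 false calls among 11332 genes. For nodule size they were 10%, 60%, 98% and 96% with 7 among 10669. For the interaction they were 10%, 56%, 90% and 98% with 18 among 12683. Of the 50 genes changed at each size, the interaction test recovered 5, 28, 45 and 49. Its 18 false calls were thus a larger share of its calls than in the other comparisons, and larger than the threshold aims at. The share of false calls among the real interaction calls may likewise exceed that aim. A list of 20 genes shifted by 0.5 was called in each of the 4 comparisons, and of 20 unchanged lists 1 was called for nodule size and 0 in each other comparison. The genes of these simulated lists were uncorrelated. In the real lists the median estimated correlation was 0.186 to 0.336 by comparison, so the simulation does not give the rate of false list calls there.

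Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, rescaling each sample to the same sum, as TPM, median-of-ratios scaling, quantile normalization, eBayes without a trend or with robust fitting, gene values summed from transcripts, a minimum log2 change of 1, big or small nodules alone, the mouse as random effect or block, livers titled mouse 3 averaged, fits over all samples, and leaving out each sample or model mouse in turn. Other splits of the samples were counted, 10 for each comparison of 3 against 3 and 100 drawn for the interaction. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Genes that share a symbol with another entry, 38 in the table, were kept by identifier.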

Results

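Messenger RNA was measured in 15 tissue samples of C57BL/6J mice, in 5 groups of 3 samples: normal livers, big tumour nodules, small tumour nodules, thymi of normal mice and thymi of tumour-bearing mice. The tumours were hepatocellular carcinoma (HCC) induced with diethylnitrosamine (DEN), a DNA-alkylating carcinogen, together with carbon tetrachloride (CCl4), a liver toxin. Normal mice received corn oil. Model mice 8, 15 and 25 each gave a big nodule, a small nodule and a thymus. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), whose sums over 13938 protein-coding genes ran from 364160 to 377984 in livers, from 331746 to 338793 in nodules and from 225669 to 257205 in thymi. The number of reads behind each value is unknown, so no counting error could be given.

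The samples carried the transcripts of their labelled organs. Alb, which encodes serum albumin, lay between 10580 and 12800 FPKM in livers, between 19490 and 26620 in nodules and between 89.96 and 135.3 in thymi. Apoa1, an apolipoprotein of hepatocytes, lay between 3059 and 3593 FPKM in livers, between 6224 and 10050 in nodules and between 26.31 and 37.97 in thymi. Rag1, part of the recombinase of developing lymphocytes, lay between 232.7 and 450.6 FPKM in thymi and between 0.1334 and 0.8023 in livers and nodules. Cd3e, a subunit of the T cell receptor complex, lay between 107.4 and 132.9 FPKM in thymi and between 0.06748 and 1.047 in livers and nodules. Pearson correlations of log2 values across genes within a group, where genes are not independent replicates, ran from 0.968 to 0.99. The normal thymus of mouse 3 correlated with the other normal thymi at 0.968 and 0.973. In the big nodule of mouse 25, mitochondrially encoded transcripts held 2.88% of summed FPKM, against 6.93 to 11.1% in the other livers and nodules.

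Nodules were compared with normal livers to describe the tumours themselves. Nodules expressed transcripts of fetal liver and liver cancer that were nearly silent in normal liver: Afp, the fetal serum protein alpha-fetoprotein, rose by 5.61 on the log2 scale (SE 0.144), from 0.302 ± 0.0927 FPKM in livers to 83.7 ± 19.7 in nodules (SD, n = 3 livers and 3 mice). Gpc3, a cell-surface proteoglycan used as an HCC marker, rose by 6.17 (SE 0.374), from 0.853 ± 0.354 to 160 ± 74.4 FPKM. At the same time the nodules lost much of the drug-metabolising, pericentral and male-specific programme of the adult liver: Cyp2c54 fell by 5.80 (SE 0.125), from 201 ± 7.47 to 3.02 ± 0.498 FPKM, and Glul, the glutamine synthetase of hepatocytes around the central vein, fell by 3.08 (SE 0.315), from 286 ± 8.01 to 36.9 ± 16.6 FPKM. Cell-cycle, interferon, antigen-presentation, extracellular matrix and macrophage transcripts rose as lists by camera, a competitive test within limma. None of these lists passed when the correlation between genes was estimated from the data (adjusted p = 0.27 to 0.395 with an estimated correlation, the P450, pericentral and male-biased lists included).

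Among 10669 genes tested with limma over 3 livers and 3 mice, whose nodules were averaged per mouse, 4316 passed an adjusted p of 0.05, 2919 upward and 1397 downward. Of these, 1011 rose and 489 fell by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. In 4233 genes (39.7%) all 6 nodules lay on the same side of all 3 livers, where chance gives 2.38% if the 6 nodules were independent and up to 10% if the nodules of a mouse move together. The share of calls that were upward depended on the scaling: it was 67.6% as deposited, with a median change over all genes of 0.13, and 79.7% after rescaling each sample to the same sum, with a median of 0.30. After quantile normalization it was 49.6%, with a median of -0.05.

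By the naming rule, the 12 largest rises and 12 largest falls were taken from genes where every nodule lay outside the range of the livers. Cyp2a4, a steroid hydroxylase of female mouse liver, rose by 7.74 (SE 0.284, adjusted p = 3.71e-06), from 5.54 ± 0.229 to 1505 ± 584.5 FPKM (n = 3 and 3). Akr1c18, a hydroxysteroid dehydrogenase, rose by 7.67 (adjusted p = 5.53e-07) and Cpe, carboxypeptidase E, by 6.97 (SE 0.107, adjusted p = 4.52e-08). Ly6d rose by 6.68, Tff3, a secreted trefoil peptide, by 6.08, the tetraspanin Tspan8 by 6.05, the lectin-like receptor Klrb1b by 5.42, Wfdc15b by 5.28 and Cyp2b9, another transcript of female liver, by 5.25. Spink1, a trypsin inhibitor, was listed at 0 in all 3 livers and lay between 18.85 and 117.1 FPKM in the nodules. Of the 12 largest falls, 7 were in major urinary protein genes: the log2 change was -6.00 in Mup12, -5.80 in Mup19, -5.76 in Mup15, -5.60 in Mup16, -5.43 in Mup1, -5.38 in Mup17 and -4.89 in Mup7. Mup transcripts held 11 to 14.3% of summed FPKM in livers and 0.694 to 2.8% in nodules. The other falls were in Cyp2c54, Cyp2c37 (-5.59) and Cyp2c50 (-5.21), in the steroid dehydrogenase Hsd3b5 (-5.57, from 129 to 2.11 FPKM) and in the fatty acid elongase Elovl3 (-5.24, SE 0.364, from 386 ± 74.2 to 10.6 ± 5.84 FPKM). Values of single Mup, Cyp2a, Cyp2b and Cyp2c genes are uncertain, because reads of near-identical copies can be split between them. On mm10, Cyp2a4 lies on chromosome 7 from 26307169 to 26315088, Cpe on chromosome 8 from 64592542 to 64693054, Gpc3 on chromosome X from 52272426 to 52613950, Afp on chromosome 5 from 90490737 to 90508907 and Cyp2c54 on chromosome 19 from 40037941 to 40073811.

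**Figure D1:**
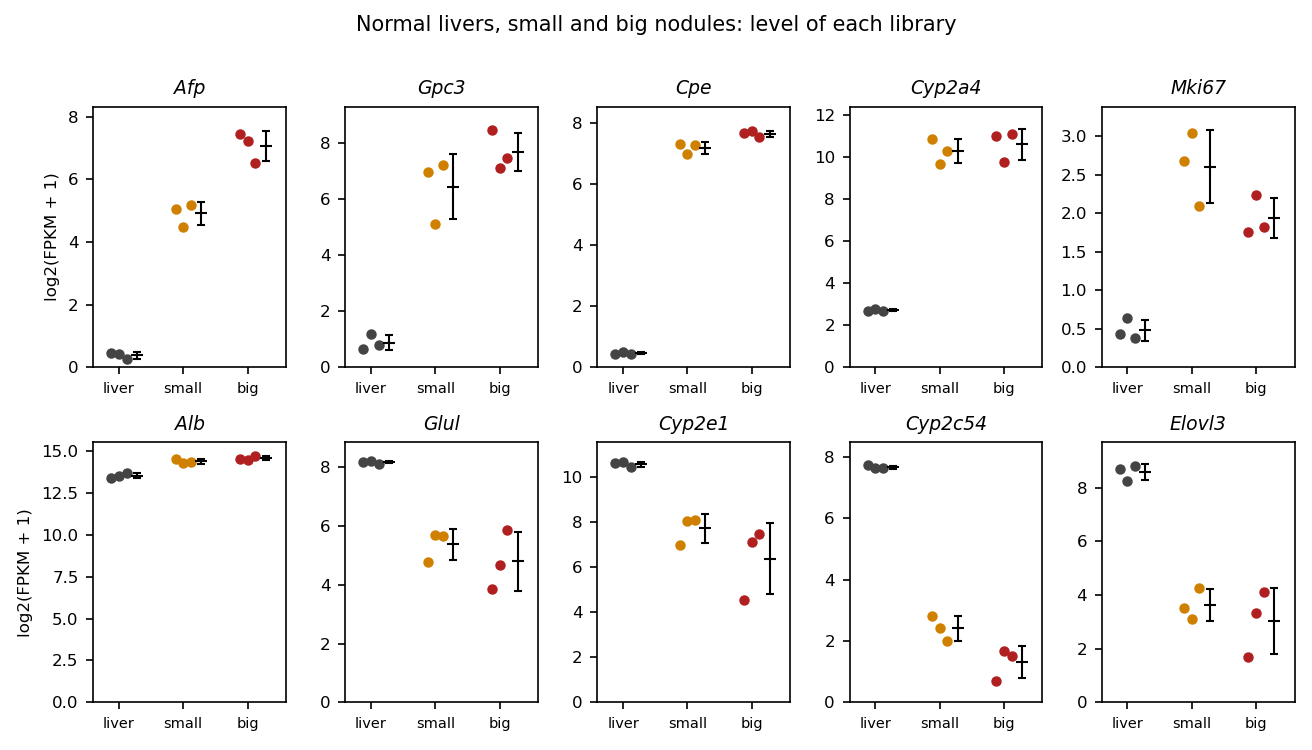
Expression as log2(FPKM + 1) of 10 genes in normal livers, small nodules and big nodules, with points for the 3 libraries of each group and bars for their mean ± SD. Afp, at a mean of 0.302 FPKM in livers and 83.7 in nodules, and Cyp2c54, at 201 and 3.02 FPKM, show the opposite directions of the tumour and adult liver transcripts.

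Gene lists were tested as groups with camera; 19 of 38 lists passed, 10 upward and 9 downward, and none passed when the correlation between genes was estimated from the data. The self-contained test fry called 25 lists, 16 of them among the 19; it did not call the fatty acid oxidation (adjusted p = 0.0536), mitochondrial (0.061) and immediate early (0.121) lists. Of 20 oncofetal and HCC marker transcripts, 19 rose, with a median of 3.89 (camera adjusted p = 1.52e-10; adjusted p = 0.27 with an estimated correlation); adjusted over the list alone, 19 rose as well. Scd2, a fatty acid desaturase, rose by 4.44. Of 20 drug-metabolising cytochrome P450 transcripts, 16 fell, with a median of -2.67 (camera adjusted p = 4.45e-13; adjusted p = 0.27 with an estimated correlation), and 16 fell when adjusted over the list alone. Cyp1a2, a pericentral member, fell by 3.38. Of 20 transcripts that are higher in male than in female liver under growth hormone control, 18 fell, with a median of -3.14 (camera adjusted p = 4.45e-13; adjusted p = 0.27 with an estimated correlation), 18 also when adjusted over the list alone. Cyp7b1 fell by 4.80 and Cyp2d9 by 1.74. Female-biased liver transcripts went mostly the other way: 7 of 11 rose and 2 fell, with a median of 2.14, and the list did not pass camera (adjusted p = 0.117) but was called by fry (0.000353). It passed camera after quantile normalization (0.0383) and without the liver numbered 2 (0.0495) or mouse 15 (0.0377). Abcd2, a peroxisomal transporter, rose by 4.10 (adjusted p = 6.47e-06).

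Lists of hepatocyte zonation and metabolism passed downward or did not pass. Of 15 pericentral and Wnt-target transcripts, 12 fell, with a median of -1.86 (camera adjusted p = 5.24e-10; adjusted p = 0.27 with an estimated correlation), among them Oat (-4.49) and Slc1a2 (-3.22). Cyp2e1, the ethanol-metabolising P450 of the same zone, fell by 3.52 (adjusted p = 0.000782), from 1519 ± 121 to 167 ± 81.6 FPKM. The periportal list split into 6 rises and 3 falls of 15 (median 0.05, -0.04 with median-of-ratios scaling; camera adjusted p = 0.97): Apoa4 rose by 3.76 and Cyp2f2 fell by 2.59. In bile acid and cholesterol metabolism, 13 of 17 transcripts fell and 3 rose (median -1.63, camera adjusted p = 1.43e-06; adjusted p = 0.27 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.49 (adjusted p = 0.000467), from 46.6 to 4.27 FPKM, and Baat, which conjugates bile acids, fell by 1.97. Of 20 urea cycle and amino acid catabolism transcripts 10 fell, with a median of -0.43 (camera adjusted p = 1.58e-05; adjusted p = 0.392 with an estimated correlation), among them Prodh (-3.15) and Slc25a15 (-1.42). Of 19 fatty acid oxidation transcripts 10 fell and 2 rose, with a median of -0.58 (camera adjusted p = 0.00113; adjusted p = 0.445 with an estimated correlation), among them Cpt2 (-1.28). Of 14 gluconeogenesis and glycogen transcripts 6 fell and 1 rose, with a median of -0.55 (camera adjusted p = 0.0182; adjusted p = 0.27 with an estimated correlation), among them G6pc (-2.14). Of 13 mitochondrially encoded transcripts 6 fell, with a median of -0.74 (camera adjusted p = 0.000111; adjusted p = 0.392 with an estimated correlation), among them mt-Nd6 (-1.11). The big nodule of mouse 25, with a mitochondrial share of 2.88%, adds to this fall: mt-Cytb was at -1.27 (adjusted p = 0.0523) with big nodules alone, -0.63 (0.0504) with small nodules alone and -0.68 (0.0565) without mouse 25. The list kept its call without model mouse 25 (median -0.50, adjusted p = 0.000625). Quantile normalization ended the calls of the urea cycle (adjusted p = 0.077), fatty acid oxidation (0.107), gluconeogenesis (0.656) and mitochondrial (0.092) lists. Glycolysis transcripts did not pass as a list, with 7 rises and 1 fall of 15 (median 0.41, camera adjusted p = 0.142, 0.0232 after quantile normalization), among them Pkm, which rose by 1.55. Nor did cholesterol synthesis, with 5 rises and 0 falls of 18 (median 0.44, camera adjusted p = 0.588), where Sqle rose by 1.46. Adjusted over the list alone, 13 bile acid, 12 pericentral, 10 urea cycle, 11 fatty acid oxidation, 6 gluconeogenesis and 9 mitochondrial transcripts fell.

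Secreted hepatocyte proteins went the other way. Of 20 transcripts 12 rose and 1 fell, with a median of 0.62 (camera adjusted p = 0.00998; adjusted p = 0.392 with an estimated correlation), among them Ahsg (1.74), Kng1 (1.68) and Trf (1.55); with small nodules alone the list lost its call (adjusted p = 0.0616). Alb rose by 0.96 (SE 0.148, adjusted p = 0.00156), from 11710 ± 1114 to 22760 ± 1553 FPKM. Quantile normalization set its change to 0, as it does for a gene of the same rank in every sample. That setting therefore cannot test the rise of Alb. Of 20 cytosolic ribosomal protein transcripts 16 rose, with a median of 0.50 (camera adjusted p = 0.000434; adjusted p = 0.361 with an estimated correlation), among them Rplp0 (0.86). Adjusted over the list alone, 14 secreted and 18 ribosomal protein transcripts rose.

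Of 20 cell-cycle transcripts 17 rose, and 19 when adjusted over the list alone, with a median of 1.35 (camera adjusted p = 1.04e-06; adjusted p = 0.27 with an estimated correlation). Mki67, a marker of dividing cells, rose by 1.79 (adjusted p = 0.000206), from 0.399 to 4.09 FPKM, and Ccnb2 by 2.19. Of 18 p53 targets 12 rose and 2 fell, with a median of 0.95 (camera adjusted p = 0.0257; adjusted p = 0.392 with an estimated correlation), among them Phlda3 (2.90) and Psrc1 (3.17). This call ended under rescaling to the same sum (adjusted p = 0.059), with small nodules alone (0.0714), with a stricter filter (0.141) and without the liver numbered 3 (0.0513), and the cell-cycle call ended under the stricter filter (0.0554). Of 25 interferon-response transcripts 19 rose, with a median of 1.00 (camera adjusted p = 0.000148; adjusted p = 0.395 with an estimated correlation), among them Usp18 (1.97) and Oas1a (2.32). Of 16 antigen processing and MHC transcripts 13 rose, with a median of 0.91 (camera adjusted p = 0.00286; adjusted p = 0.392 with an estimated correlation), among them H2-Aa (1.73) and H2-D1 (0.92). Adjusted over the list alone, 12 p53, 20 interferon and 13 MHC transcripts rose.

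Among non-parenchymal groups, 13 of 18 stellate cell and fibrosis transcripts rose and 1 fell, with a median of 0.96 (camera adjusted p = 0.000581; adjusted p = 0.392 with an estimated correlation). Col1a1, a chain of fibrillar collagen, rose by 2.08 (adjusted p = 0.0011), from 1.28 to 8.59 FPKM. Of 13 macrophage and monocyte transcripts 12 rose, with a median of 1.00 (camera adjusted p = 0.0028; adjusted p = 0.392 with an estimated correlation): Cd14 rose by 2.44 and C1qb by 1.25. Of 14 endothelial transcripts 10 rose, with a median of 0.78 (camera adjusted p = 0.00582; adjusted p = 0.392 with an estimated correlation), among them Lyve1 (2.03) and Cdh5 (1.19). Immediate early transcripts, induced within minutes of a stimulus, went down: 6 of 13 fell and 1 rose, with a median of -0.51 (camera adjusted p = 0.00437, 0.077 after quantile normalization; adjusted p = 0.445 with an estimated correlation). Fos fell by 3.07 and Egr1 by 2.33, and Ier3 rose by 2.53. Adjusted over the list alone, 14 fibrosis, 12 macrophage and 10 endothelial transcripts rose and 6 immediate early transcripts fell.

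Groups whose list did not pass still held genes that did. Spp1, the secreted matrix protein osteopontin, rose by 2.71 (adjusted p = 0.00175), from 34.03 to 269 FPKM, in a cholangiocyte list with 5 rises of 8 (camera adjusted p = 0.163). Vcam1 rose by 2.14 and Cxcl12 fell by 1.93 in the list of chemokines and homing receptors, with 10 rises and 2 falls of 14 (camera adjusted p = 0.0625, 0.038 without mouse 15). In the erythroid list, which did not pass either, Hba-a1 rose by 1.52, Hba-a2 by 1.42 and Hbb-bt by 1.13, while Alas2 fell by 2.69. The Hba-a2 and Hbb-bt calls ended under some alternatives. The Kupffer cell (camera adjusted p = 0.947), dendritic cell (0.142) and tumour-associated immune regulation (0.118) lists did not pass. Nor did the unfolded protein and heat-shock list, with 3 rises and 5 falls of 18 (median -0.18, camera adjusted p = 0.142, 0.0209 without the liver numbered 5), where Trib3 rose by 4.16. Cd274, which encodes the checkpoint ligand PD-L1, rose by 0.56 (adjusted p = 0.00572), from 0.567 to 1.31 FPKM, but not after quantile normalization (0.15, adjusted p = 0.339). Of 5 T and NK cell transcripts above the filter only Ccl5 rose, by 2.01 (camera adjusted p = 0.163 for the list); adjusted over the list alone 3 rose, and all 5 were above 0. The acute phase list held 6 rises and 9 falls of 20, and its median (0.01), mean (-0.22) and test (downward, camera adjusted p = 0.343) differed in sign: Il1rn rose by 2.60 and Hamp fell by 2.56. In fatty acid synthesis and storage, with 6 rises and 3 falls of 18 (median 0.22, test downward, camera adjusted p = 0.947), Lpl rose by 3.85 and Thrsp fell by 2.91. The metallothionein Mt2 rose by 4.18 in a glucocorticoid list that did not pass (camera adjusted p = 0.703). The nodules and the livers came from different mice, and the design holds no liver exposed to DEN and CCl4 without tumour.

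**Figure D2:**
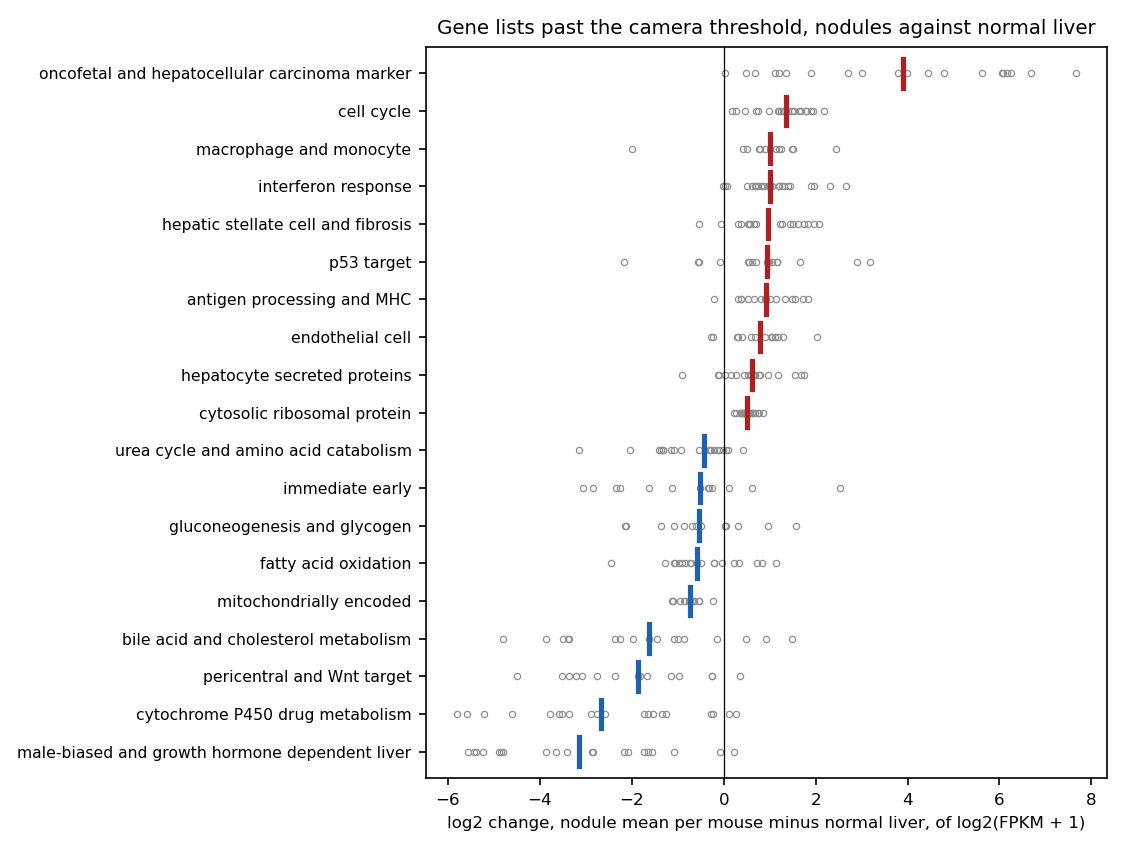
Log2 change of log2(FPKM + 1), nodules minus normal livers, for the 19 gene lists that camera called, with open points for the genes of a list and a bar at its median, red where called upward and blue where downward. The medians run from -3.14 in male-biased transcripts to 3.89 in oncofetal and HCC marker transcripts.

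The central question of the series was how a liver tumour alters gene expression in the thymus, where T cells develop. No single gene passed the test between model and normal thymi. Of the main thymocyte stage, Rag1 was at 339.5 ± 109 FPKM in normal and 383 ± 39.0 in model thymi (SD, n = 3 and 3, log2 change 0.22, SE 0.233). Other transcripts of that stage lay on both sides of no change, with Ptcra at -0.61 (SE 0.158) and Tcf12 at 0.63 (SE 0.368). As groups, transcripts of mature thymocytes leaving the thymus, of mesenchyme, of vessels and of macrophages ranked higher in model thymi, by medians of 0.34 to 0.50. The lists of the unfolded protein and heat-shock response, of ribosomal proteins and of immediate early genes ranked lower, by medians of -0.26 to -0.29. These rankings came from camera; none of the lists passed with an estimated correlation (adjusted p = 0.76 with an estimated correlation for each) or with fry, limma's self-contained test, and the macrophage call ended without the normal thymus of mouse 2 (0.0974). Gzmb, granzyme B of killer T cells, was at 2.04 ± 0.556 FPKM in normal and 1.98 ± 0.387 in model thymi.

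Of 11332 genes tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.099. At an unadjusted p under 0.05 there were 1159 (10.2%), 758 higher and 401 lower, where chance gives 567. In 2132 genes (18.8%) the groups did not overlap, where chance gives 10%. Both chance values are averages. Genes vary together, with a median estimated correlation of 0.278 within the lists tested in thymus, so a single chance split can lie far from these averages. The 2 counts were not set beside those of other splits, so no diffuse response can be read from the excess. A simulation with the same design changed genes with a mean of at least 5 FPKM. It recovered 28% of 1.5-fold, 66% of 2-fold and 98% of 4-fold changes. The count of 0 thus excludes neither smaller changes nor changes of 2-fold and more in single genes. A fit that took its spread from all 15 samples called 36 genes, 26 upward and 10 downward, with Tfdp2 (1.87), Apod (1.36) and Fscn1 (1.56) at the smallest p. Apod was named after its value was seen. That fit pooled the spread of thymi with that of livers and nodules and counted the samples of a mouse as independent. Without the normal thymus of mouse 2, 11 genes passed.

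The smallest p values were those of Fscn1, Tfdp2 and Bach2 among higher genes. Fscn1, the actin-bundling protein fascin of mature dendritic cells, was at 2.98 ± 0.455 FPKM in normal and 10.8 ± 1.54 in model thymi (log2 change 1.56, SE 0.153, adjusted p = 0.099), on chromosome 5 from 142960343 to 142973185 of mm10. Tfdp2, a partner of E2F transcription factors, was at 1.12 and 6.60 FPKM (log2 change 1.87, adjusted p = 0.234), and Bach2, a repressor of effector T cell differentiation, at 0.288 and 1.82 FPKM (log2 change 1.15, adjusted p = 0.435). Among lower genes, Kctd20 was at 21.02 and 8.22 FPKM (log2 change -1.23), the cholesterol synthesis enzyme Cyp51 at 9.87 and 5.08 FPKM (-0.84) and Slx1b at 5.16 and 2.43 FPKM (-0.84), each with an adjusted p of 0.435.

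The thymus genes fixed in advance lay on both sides of no change, and none passed. The coreceptors Cd4 and Cd8a had log2 changes of 0.26 (SE 0.207) and -0.06 (SE 0.119). In thymic epithelium, Foxn1, its master regulator, had a log2 change of -0.18 (SE 0.190). Psmb11, the cortical proteasome subunit, was at 41.9 ± 5.93 FPKM in normal and 28.4 ± 7.29 in model thymi (-0.57, SE 0.206, adjusted p = 0.481), and Aire, the medullary regulator of self-antigens, at 2.47 ± 0.278 and 4.04 ± 0.804 FPKM (0.53, SE 0.157, adjusted p = 0.481). The log2 change was -0.31 (SE 0.212) in the chemokine Cxcl10 and 0.30 (SE 0.217) in its receptor Cxcr3, which guide activated T cells. It was -0.02 (SE 0.175) in Gzmb, 0.27 (SE 0.163) in Prf1, which encodes perforin, and -0.02 (SE 0.171) in the checkpoint receptor Pdcd1. For the death receptor Fas it was -0.11 (SE 0.165), for its ligand Fasl 0.07 (SE 0.172), and for Mki67 0.17 (SE 0.19).

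**Figure D3:**
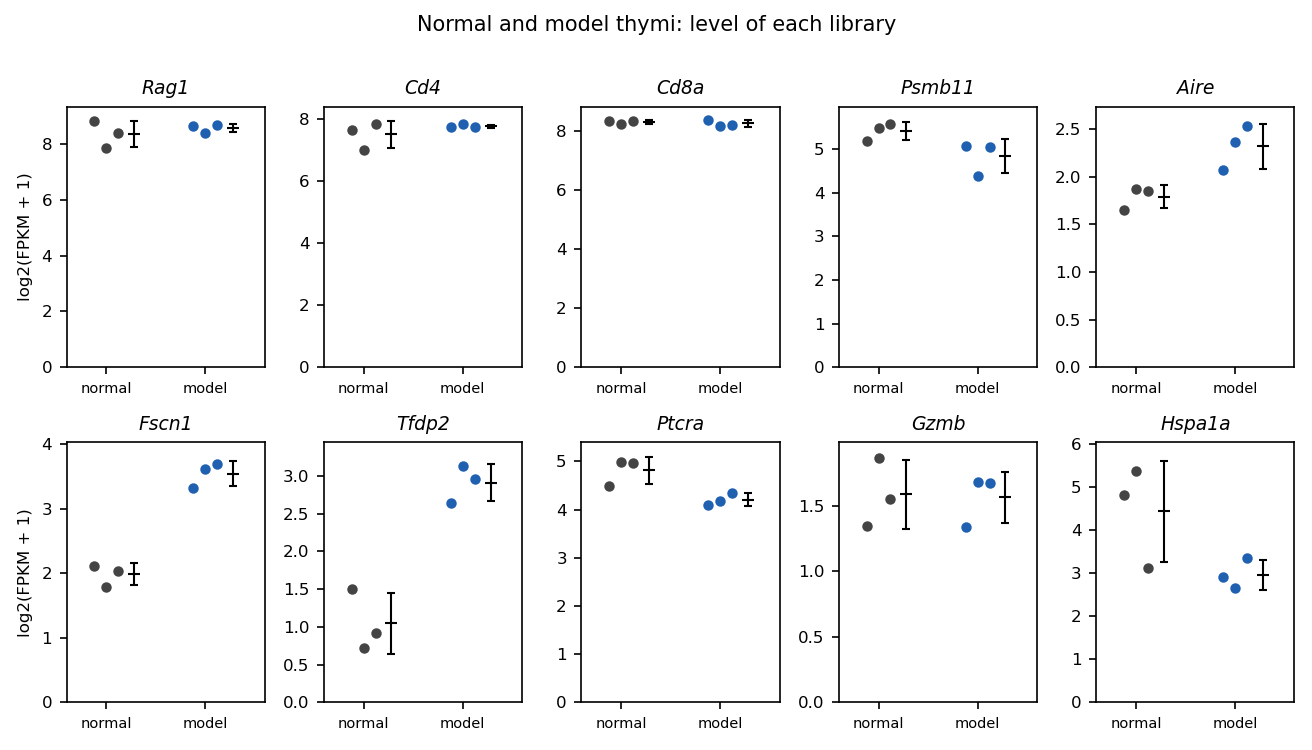
Expression as log2(FPKM + 1) of 10 genes in normal and model thymi, with points for the 3 libraries of each group and bars for their mean ± SD. Fscn1, at 2.98 and 10.8 FPKM, separates the groups, while Rag1, at 339.5 and 383 FPKM, overlaps; neither passed the test.

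Of 33 lists tested in thymus, 15 passed camera, 8 upward and 7 downward; none did with an estimated correlation (adjusted p = 0.76 with an estimated correlation for each) or with fry (smallest adjusted p = 0.366). Mature thymocyte and egress transcripts were shifted upward, with a median of 0.34 and 15 of 16 members above 0 (camera adjusted p = 2.92e-05); 4 passed when adjusted over the list alone, and Gimap3 was at 0.69 and Il7r, the receptor of interleukin-7, at 0.54. All 12 mesenchyme and fibroblast transcripts were above 0, with a median of 0.50 (camera adjusted p = 2.92e-05), among them Dcn at 0.79 and Postn at 0.47. All 6 endothelial transcripts were above 0, with a median of 0.43 (camera adjusted p = 0.00067), and all 6 passed when adjusted over the list alone, among them Eng at 0.49 and Cdh5 at 0.45. Of 14 macrophage and monocyte transcripts 12 were above 0, with a median of 0.40 (camera adjusted p = 0.000983); Cd68 was at 0.61 and Adgre1 at 0.62, and 3 passed when adjusted over the list alone. All 11 B cell transcripts were above 0, with a median of 0.29 (camera adjusted p = 0.00284), among them Cd79a at 0.68. Smaller upward shifts were those of dendritic cells (median 0.31, camera adjusted p = 0.0463), cytotoxic effector T cells (0.22, 0.0449; Klrd1 at 0.76) and checkpoint molecules (0.13, 0.0463; Btla at 0.51 and Havcr2 at 0.46).

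Downward shifts had other members. Of 17 unfolded protein and heat-shock transcripts 15 were below 0, with a median of -0.28 (camera adjusted p = 2.92e-05; adjusted p = 0.76 with an estimated correlation), led by Hspa1a (-1.47), Hspa1b (-1.53) and Hsp90aa1 (-1.24). All 20 ribosomal protein transcripts were below 0, with a median of -0.26 (camera adjusted p = 2.92e-05), and all 14 immediate early transcripts, with a median of -0.29 (camera adjusted p = 0.000699; Nr4a1 at -0.52, Jund at -0.43). Of 26 cell-cycle transcripts 18 were below 0, with a median of -0.15 (camera adjusted p = 0.000758). The members with the smallest p were Ccne2 (-0.61), Rrm2 (-0.33) and Pcna (-0.41), and none of them passed. The adipocyte list (median -0.27, camera adjusted p = 0.0165; Cidec at -0.87, Adipoq at -0.88) and the neutrophil list (median -0.49, camera adjusted p = 0.0229; S100a8 at -1.04) were lower. So were hepatocyte transcripts seen at a low level in thymus (median -0.21, camera adjusted p = 0.0463). For these lists too the adjusted p was 0.76 with an estimated correlation.

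The lists of developing T cells and epithelium did not pass. Double-positive thymocyte transcripts had a median of 0.06 while the test pointed downward (camera adjusted p = 0.89); Ptcra, the pre-T cell receptor chain, was at -0.61 (SE 0.158, adjusted p = 0.481). T cell receptor components had a median of 0.02, also with a downward test (0.89; -0.02 with median-of-ratios scaling), and negative selection transcripts a median of -0.02 (0.22; 0.03 after rescaling to the same sum). Cortical epithelium had a median of 0.12 (0.707), medullary epithelium 0.10 (0.37), regulatory T cells 0.14 (0.433), apoptosis 0.00361 with a downward test (0.475), interferon response 0.21 (0.137) and chemokines and homing receptors 0.19 (0.0954). Tumour-associated immune regulators had a median of 0.08, a mean of -0.10 and a downward test (0.547), with Il1b at -1.87. Some of these lists passed in other settings. Without the normal thymus of mouse 3 the medullary epithelium (median 0.31, adjusted p = 0.000177), chemokine (0.39, 0.000177), MHC (0.29, 0.000476; 0.15, 0.232 with it) and interferon (0.20, 0.0404) lists passed upward. Without the normal thymus of mouse 5 the negative selection list (-0.14, 0.0442) passed, and so did mitochondrially encoded transcripts (0.37, 0.0363; 0.27, 0.086 with it). Without the model thymus of mouse 8 the interferon (0.33, 0.0108) and chemokine (0.31, 0.0272) lists passed, without that of mouse 15 the chemokine list (0.15, 0.0454) and without that of mouse 25 the erythroid list (1.14, 0.0425; 0.60, 0.433 with it). After quantile normalization the T cell receptor (0.13, 0.0172), chemokine (0.19, 0.012), MHC (0.20, 0.000691) and mitochondrial (0.30, 0.00996) lists passed. The mature thymocyte, mesenchyme, endothelial, heat-shock, ribosomal protein and immediate early lists passed camera without any single thymus and under each scaling.

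The other 9 calls ended when single libraries were left out. Without the normal thymus of mouse 2, 8 lists passed, and the macrophage (adjusted p = 0.0974), B cell (0.0747), dendritic cell (0.0605), cytotoxic (0.426), checkpoint (0.162), neutrophil (0.352) and hepatocyte (0.352) calls ended. The medians without it were 0.31 for dendritic cells, 0.28 for B cells, 0.18 for cytotoxic and 0.16 for checkpoint transcripts, beside 0.31, 0.29, 0.22 and 0.13 with it. They were 0.29 for macrophages, -0.08 for neutrophils and -0.13 for hepatocyte transcripts, beside 0.40, -0.49 and -0.21. Without the normal thymus of mouse 5 the cell-cycle (0.0915), adipocyte (0.271), B cell (0.0603), dendritic cell (0.195), cytotoxic (0.323), checkpoint (0.14) and neutrophil (0.0956) calls ended. The hepatocyte call ended without the normal thymus of mouse 3 (0.445). Without the model thymus of mouse 8 the adipocyte (0.0748) and hepatocyte (0.116) calls ended. Without that of mouse 15 the cytotoxic, checkpoint and neutrophil (0.093 each) and B cell (0.0616) calls ended, and without that of mouse 25 the cytotoxic and checkpoint (0.0624 each) and hepatocyte (0.16) calls. Quantile normalization ended the cell-cycle (0.102), cytotoxic (0.0569), checkpoint (0.1) and hepatocyte (0.12) calls.

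**Figure D4:**
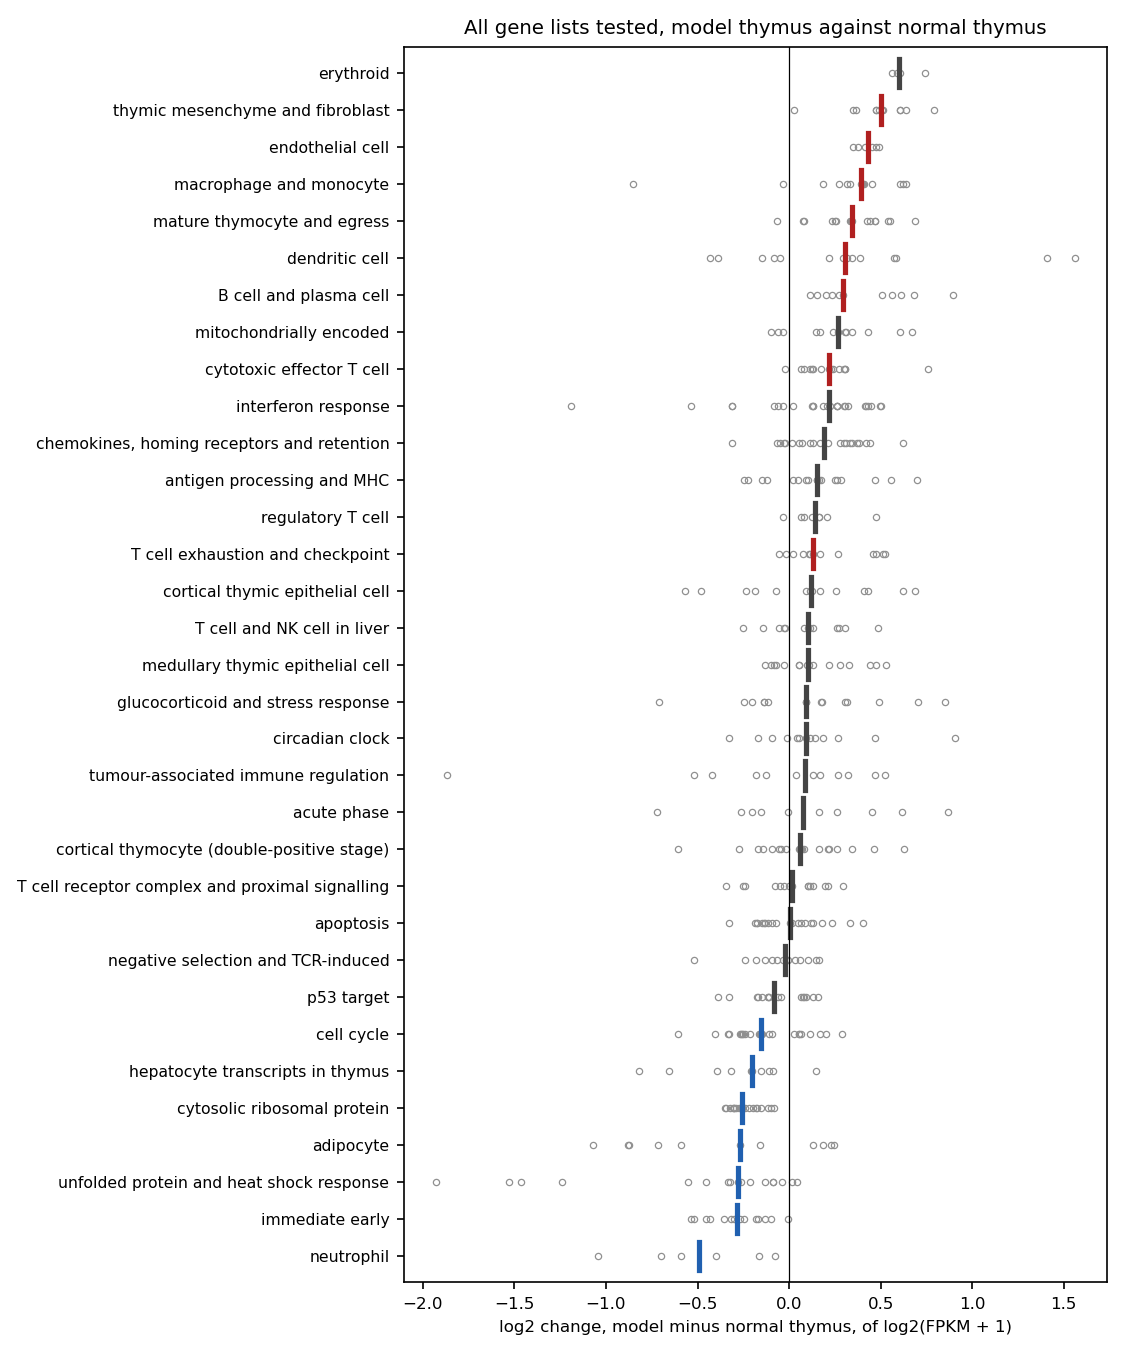
Log2 change of log2(FPKM + 1), model minus normal thymi, for each gene list tested, with open points for its genes and a bar at its median, red or blue where camera called it upward or downward and dark grey otherwise. The called medians run from -0.49 in neutrophil transcripts to 0.50 in mesenchyme transcripts.

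Big and small nodules of the same 3 mice were compared to ask whether expression differs with tumour size. No gene passed, but Afp was higher in the big nodule of each of the 3 mice, at 138 ± 42.4 FPKM in big and 29.7 ± 7.43 in small nodules (log2 change 2.16, SE 0.287, adjusted p = 0.36; SD, n = 3 and 3). That test did not use the pairing by mouse, and with the mouse as a block the adjusted p of Afp was 0.668. Transcripts of secreted hepatocyte proteins, cholesterol synthesis and HCC markers ranked higher in big nodules. Transcripts of cytochrome P450s, male-biased liver genes, the cell cycle and macrophages ranked lower. None of these lists passed with an estimated correlation (adjusted p = 0.542 to 0.606 with an estimated correlation) or with fry. Leaving out mouse 8 ended the male-biased (median -0.23, adjusted p = 0.245) and cell-cycle (-0.28, 0.129) calls, mouse 15 the cholesterol (0.07, 0.0971), HCC marker (0.09, 0.0676) and macrophage (-0.23, 0.0736) calls, and mouse 25 the macrophage call (-0.20, 0.523).

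Of 10669 genes tested with limma, 0 passed, with a smallest adjusted p of 0.0971; 431 (4.04%) had an unadjusted p under 0.05, 155 higher and 276 lower. The groups did not overlap in 981 genes (9.19%). Independent nodules would give 533 genes and 10% by chance, but the 2 nodules of a mouse deviated alike (correlations of 0.261 to 0.325), which lowers both, so no shortfall can be read from them. Slc43a2, an amino acid transporter, was at 0.283 FPKM in small and 1.94 in big nodules (log2 change 1.19, adjusted p = 0.0971), and Psat1, an enzyme of serine synthesis, at 3.40 and 8.74 FPKM (1.16, 0.948). The transporter Slc36a1 was at 6.09 and 1.32 FPKM (-1.60, 0.0971), Casp12 at 5.27 and 2.36 FPKM (-0.89, 0.948) and Lst1 at 1.82 and 0.717 FPKM (-0.72, 0.948). Gpc3 had a log2 change of 1.25 (SE 0.584), Cyp2e1 of -1.34 (SE 0.735), Cyp7a1 of -0.93 (SE 0.627), Mki67 of -0.66 (SE 0.259), Glul of -0.59 (SE 0.492) and Spp1 of -0.61 (SE 0.717). Alb (0.19), Col1a1 (0.09) and Cd274 (-0.07) were closer to no change. With the mouse as a block, the adjusted p was 0.294 for Slc36a1 and 0.379 for Slc43a2. A fit over all 9 liver and nodule samples called 2 genes, Slc36a1 (adjusted p = 0.0227) and Afp (0.0474). That fit also took its spread from livers, where Afp was at 0.302 ± 0.0927 FPKM. Without mouse 8, 1 gene passed (Gm20431 at 4.38), and without mouse 25 another (AC149222.1 at -4.13); both were named after their values were seen.

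Of 38 lists 15 passed camera for nodule size, 6 upward and 9 downward; none passed with fry (smallest adjusted p = 0.549) or with an estimated correlation (adjusted p = 0.542 to 0.606 with an estimated correlation for the 15). Of 20 secreted hepatocyte protein transcripts 19 were higher in big nodules, with a median of 0.23 (camera adjusted p = 1.47e-07; Ttr at 0.53). All 18 cholesterol synthesis transcripts were higher, with a median of 0.47 (camera adjusted p = 1.18e-06; Lss at 0.72), which dropped to 0.07 without mouse 15 (0.0971). HCC markers had a median of 0.32 (camera adjusted p = 2.73e-05), and of 0.09 without mouse 15 (0.0676), and Afp passed when adjusted over the list alone. Ribosomal proteins (median 0.12, Rps14 at 0.51), unfolded protein response (0.08, Hspa5 at 0.56) and p53 targets (0.09) were shifted upward as well; leaving out mouse 8 ended the unfolded protein (median 0.00198, adjusted p = 0.0587) and p53 (0.06, 0.117) calls, and leaving out mouse 15 the p53 call (0.07, 0.572). Of 20 cytochrome P450 transcripts 18 were lower, with a median of -0.67 (camera adjusted p = 0.00011; Cyp1a2 at -1.38), and of 20 male-biased transcripts 19, with a median of -0.69 (camera adjusted p = 0.000801; -0.23, 0.245 without mouse 8; Mup20 at -1.17). Adjusted over the list alone, 2 male-biased transcripts passed. Cell-cycle transcripts had a median of -0.33 (camera adjusted p = 0.000495; -0.28, 0.129 without mouse 8), NRF2 and glutathione transcripts of -0.39 (0.00186; Nqo1 at -1.04), bile acid transcripts of -0.48 (0.00701; -0.26, 0.187 without mouse 8) and pericentral transcripts of -0.29 (0.0226; -0.12, 0.418 without mouse 8). Macrophage (-0.27, camera adjusted p = 0.0131) and Kupffer cell (-0.31, 0.0484) transcripts lost their calls without mouse 25 (-0.20, 0.523 and -0.01, 0.679), and macrophages without mouse 15 (-0.23, 0.0736). The same held for mitochondrially encoded transcripts (-0.54, 0.000555; -0.10, 0.557 without mouse 25), whose share in the big nodule of mouse 25 was 2.88%. Without mouse 8 glycolysis transcripts (0.33, 8.22e-05) passed, and without mouse 25 erythroid transcripts (-0.77, 5.87e-06). With the mouse as a block, the Kupffer cell call ended (0.0786) and interferon-response transcripts (median -0.16, camera adjusted p = 0.0844) passed (0.0301).

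The response to the model was also compared between organs, to ask where the thymus response differed from that of the nodules. The difference between the thymus change and the nodule change passed in 2815 of 12683 genes tested with limma's interaction term, with 967 above and 1848 below 0. Tumour transcripts such as Afp (interaction -5.48), Cpe (-6.44) and Gpc3 (-5.18) and liver transcripts such as Cyp2c54 (5.85), Hsd3b5 (5.50) and Oat (4.45) led it. Afp, Gpc3, Cyp2c54 and Hsd3b5 did not pass the filter in thymus, so their interaction rests mainly on the nodule change; Gpc3 had means of 0.582 FPKM in normal and 2.45 in model thymi. Oat, ornithine aminotransferase, is expressed in both organs: it fell by 4.49 in nodules and was at 44.4 and 42.8 FPKM in normal and model thymi. Mki67, which rose in nodules, had an interaction of -1.62 (SE 0.28, adjusted p = 0.00129). Of 21 lists tested in both organs, 7 passed: the cell-cycle (median -1.29), p53 (-0.87), MHC (-0.86), ribosomal protein (-0.75) and interferon (-0.72) lists were lower in the thymus response, and the mitochondrial (1.14) and immediate early (0.53) lists higher. None passed with an estimated correlation (smallest adjusted p = 0.22 with an estimated correlation), and fry called 10, among them these lists except the immediate early one (adjusted p = 0.303). The share of calls above 0 was 34.4%, with a median of -0.08 over all genes, and 46.4% after quantile normalization, with a median of 0.04.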

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

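The interaction test was planned; the tests of explanations and the counts of other splits given here were chosen only after the results were seen.

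Transcripts higher in male than in female liver fell in nodules, with a median of -3.14 and 18 of 20 members past the threshold. A difference in sex is argued against by 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y), whose summed FPKM lay between 34.5 and 42.3 in the 9 liver and nodule samples, a lowest-to-highest ratio of 0.815. Reads shared between paralogs are argued against by the 10 members outside the Mup, Cyp4a12 and Serpina1 families, which all fell, with a median of -2.51, and by the sum over 19 Mup genes, which changed by -3.04 (SE 0.217). Fewer hepatocytes in nodules would lower secreted hepatocyte proteins as well, whose median change was 0.62. A loss of the growth hormone pattern in tumour cells may account for it, as may exposure to DEN and CCl4 or age, which were not tested, since no model liver without tumour was analysed here.

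Stromal and macrophage lists were shifted upward and ribosomal, adipocyte and neutrophil lists downward in model thymi, with no gene past the threshold. The macrophage (camera adjusted p = 0.0974) and neutrophil (0.352) calls ended without the normal thymus of mouse 2, and the adipocyte call (0.271) without that of mouse 5. Fewer thymocytes would raise the markers of all other cell types alike. The mean change of the adipocyte list, however, was -0.769 relative to the endothelial list (SE 0.211), but adipocytes could come from tissue around the thymus. Cortical (-0.328, SE 0.15) and medullary epithelium (-0.282, SE 0.209), neutrophils (-0.921, SE 0.471) and erythroid cells (0.199, SE 1.04) do not decide this. The furthest of these lay at -2.19 SE, too close to be told apart with 3 mice per group. The mesenchyme (0.0607, SE 0.129), macrophage (-0.13, SE 0.186), dendritic cell (-0.0979, SE 0.0993) and B cell (-0.0142, SE 0.232) lists did move with the endothelial list, as fewer thymocytes would give, so that stays open for these upward shifts. The normal thymus of mouse 3, which correlated least with its group, is not the source of the shifts, since 14 of the 15 lists kept their call without it, where 18 passed, against 8 without the normal thymus of mouse 2. A change of the thymic stroma in tumour-bearing mice, and a difference between libraries that moves many genes together, stay open. No list passed with an estimated correlation (adjusted p = 0.76 for each). At these sample sizes that test called no list in any comparison, so it does not separate these explanations.

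The heat-shock chaperones Hspa1a, Hspa1b, Hsph1, Hsp90aa1 and Dnajb1, chosen after their values were seen from a list that did not pass in nodules (3 rises and 5 falls of 18, median -0.18, camera adjusted p = 0.142, 0.0209 without the liver numbered 5), were lower in model mice in both organs, with a median change of -1.66 in nodules, where 4 of 5 passed, and of -1.47 in thymus, where none of the 5 passed (adjusted p = 0.481 for each). The mean of the 5 in thymus lay 1.02 to 1.25 above that in nodules of the same mouse, and with normal livers and thymi linked by column number the change differed between organs by 0.28 (SE 0.104), beside -1.60 in nodules. The titles do not give that link, other links gave an SE of up to 0.896 and the choice of the 5 favours a small difference, so tissue handling and a state of the whole animal stay open; time of harvest, dissection, age and a systemic effect of tumour or toxin were not tested. In nodules the adjusted p was 0.0565 for Hspa1a, and Dnajb1 lost its call without the liver numbered 2 (0.0541) or 3 (0.0548). The model thymus of mouse 15 is not the whole source, since the thymus median without it was -1.04 (SE 0.477); without other libraries it ran from -2.12 to -0.997.

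For nodules against livers, 1 of the 10 splits of the 6 values, the real one, gave as many as 4316 genes and the highest other gave 0; 10 splits are too few for a share under 0.05. For thymus the real count was 0, which each of the 10 splits reaches by definition, so this count tests nothing. The highest other split gave 5. For nodule size the real count was 0 as well, so the count of splits is again void. Of the 4 splits that part all 3 mouse pairs the highest other gave 0, while splits that keep a pair together gave up to 3.

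The response to the model differed between organs, by the interaction test, in 2815 genes. Of these, 2563 were also called in nodules against livers, all with the opposite sign, which the shared livers and nodules build in. Among the 2006 tested in both organs the median absolute change was 0.916 in nodules and 0.155 in thymus; over all genes tested, which this test did not select, it was 0.341 and 0.162. Of 100 drawn splits, 6, the real one included, gave at least as many calls as the real 2815, and the highest other gave 3581, so chance is not excluded by this count. All 6 were among 11 drawn splits that keep the real division of livers and nodules (2556 to 3581 calls), and splits that do not keep it gave at most 2, so the count points to the division of livers and nodules and not to that of the thymi.

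The same test set apart these genes, as thymus change minus nodule change: Cyp2c54 (5.85), Cyp2c37 (5.56), Hsd3b5 (5.50), Cyp2c50 (5.06), Mup16 (5.04), Elovl3 (4.98), Mup19 (4.85), Mup12 (4.83), Mup15 (4.63), Cyp2c29 (4.62), Oat (4.45) and Mup1 (4.36). Below 0 were Akr1c18 (-7.82), Cyp2a4 (-7.72), Ly6d (-6.94), Cpe (-6.44), Tff3 (-5.91), Tspan8 (-5.75), Afp (-5.48), Spink1 (-5.39, with livers listed at 0), Klrb1b (-5.37), Cyp2b9 (-5.26), Gpc3 (-5.18), Wfdc15b (-5.12) and Mki67 (-1.62). At a pseudocount of 0.01, Cyp2c29 (adjusted p = 0.172), Cyp2c50 (0.0658), Elovl3 (0.283), Mup1 (0.109), Mup12 (0.731), Mup15 (0.632), Mup16 (0.055), Mup19 (0.124) and Wfdc15b (0.134) lost their call. At a pseudocount of 0.1, Mup1 (0.0683), Mup12 (0.191), Mup15 (0.232) and Mup19 (0.0602) already lost it. After rescaling to the same sum, Mup12 (0.075) and Mup15 (0.107) lost their call. Cyp2c54, Cyp2c37, Hsd3b5, Cyp2c50, Mup16, Elovl3, Cyp2c29, Akr1c18, Tspan8, Afp, Klrb1b, Cyp2b9, Gpc3 and Wfdc15b did not pass the filter in thymus, so their difference rests mainly on the nodules. In part it rests on the thymus for Gpc3, with means of 0.582 FPKM in normal and 2.45 in model thymi, and for Mup16, with 1.58 and 0.514. Ly6d, on the other hand, is expressed in thymus, at 371 FPKM in normal and 303 in model thymi. Of the others past the filter in thymus, Mup12 (-1.17, SE 0.703), Mup15 (-1.13, SE 0.786), Mup1 (-1.07, SE 0.708), Mup19 (-0.941, SE 0.679) and Spink1 (0.856, SE 0.295) had the largest thymus changes. These made the difference between organs smaller than the nodule change alone.

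The lists that differed between organs by the same test were the cell cycle (median -1.29), p53 targets (-0.87), antigen processing and MHC (-0.86), ribosomal proteins (-0.75), interferon response (-0.72), immediate early genes (0.53) and mitochondrially encoded transcripts (1.14). With an estimated correlation their adjusted p ran from 0.22 to 0.738. The immediate early call ended without the liver numbered 5 (adjusted p = 0.17), the normal thymus of mouse 2 (0.113) or 5 (0.0531), or mouse 15 (0.0782) or 25 (0.0659). It also ended after quantile normalization (0.193), with median-of-ratios scaling (0.0513), with a filter at 5 FPKM (0.0649) and with values summed from transcripts (0.0522), and the p53 call ended with that filter (0.0929).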

How the results depend on the processing

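Of the counts of genes past the threshold, that for nodules against livers fell to 2606 with a filter at 5 FPKM, which tests fewer genes, and to 1500 with a minimum log2 change of 1, which is stricter by construction; that minimum left 1411 genes in the interaction. For thymus the count went from 0 to 36 when the spread came from all 15 samples, and leaving out each sample gave 0 to 11. For nodule size it went from 0 to 2 when all 9 liver and nodule samples entered, and leaving out each mouse gave 0 to 1. Both wider fits pool the spread over more groups and count the samples of a mouse as independent. Whether this accounts for the added calls was not tested. An estimated correlation left 0 lists in each of the 4 comparisons, and fry left 0 in thymus and for nodule size but called 25 in nodules against livers, 16 of them with camera, and 10 in the interaction, 6 of them with camera. Leaving out each thymus sample gave 8 to 18 lists. With the mouse as a block, 0 genes and 15 lists passed for nodule size and 3034 genes in the interaction, and the block changed no list's call in these 2 comparisons other than those of the Kupffer cell and interferon lists for nodule size. With the mouse as a random effect over the 6 nodules, against livers, the chemokine list passed (adjusted p = 0.0373) and mt-Cytb lost its call (0.0703). Of single genes named, 72 of 3273 values in nodules fell below the threshold under an alternative and 18 passed it; 15 of 480 in the interaction fell below it, mostly at pseudocounts of 0.01 or 0.1, with Elovl3 at 3.36 (adjusted p = 0.283) under the former. In thymus 10 of 2375 and for nodule size 2 of 2316 passed under an alternative. Of the lists under camera with its preset correlation, 12 of 755 values in nodules, 42 of 558 in thymus, 23 of 565 for nodule size and 10 of 419 in the interaction lost their call, and 12, 16, 6 and 15 gained one. No called gene or list turned its direction under any alternative run. Unknown depth limits what can be said of genes near 0 FPKM. Tests on read counts were not run, since the values are FPKM.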

Other observations

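These genes were chosen after their values were seen, and no explanation was tested. Dbp, a clock output gene, was between 0.6654 and 1.164 FPKM in the 3 normal livers. It was at 0.3308 in the big and 1.836 in the small nodule of mouse 8, at 24.11 and 12.58 in those of mouse 15, and at 81.88 and 61.43 in those of mouse 25. Nr1d1, a clock repressor, was between 5.757 and 15.33 FPKM in normal livers and at 7.288 and 11.49 FPKM in the nodules of mouse 8, 27.63 and 28.93 in those of mouse 15 and 53.48 and 59.78 in those of mouse 25. The model thymi had the same order for Nr1d1, with 2.62 in mouse 8, 5.966 in mouse 15 and 8.572 in mouse 25. The clock list passed in none of the comparisons.

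Car3, carbonic anhydrase 3, lay between 1160 and 1279 FPKM in livers and between 11.57 and 175.8 in nodules. Lcn2, an acute phase protein, was at 38.31, 9.77 and 1.721 FPKM in the livers numbered 2, 3 and 5, and between 112.9 and 172.1 in nodules. Apoa4 lay between 129.3 and 264.4 FPKM in livers and between 1912 and 3295 in nodules. In thymus, Sirpa, a receptor of myeloid cells, was at 10.99, 1.827 and 3.357 FPKM in the normal mice 2, 3 and 5 and between 11.72 and 14.19 in the model mice. Mup3, a liver transcript, ranged from 1.304 to 21.8 FPKM over the 6 thymi.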
